A study of Homo sapiens with 12 samples.

How the data were processed

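RNA was measured in 12 samples of MDA-MB-231, an established human breast cancer cell line of the triple-negative, basal-like and mesenchymal kind, on Affymetrix 3′ expression arrays of 22277 probe sets, with 1 array per sample. Per the labels' protocols, the cells received lentiviral particles carrying a short hairpin RNA (shRNA), total RNA was taken with a column kit and a DNase step, and biotin-labelled cRNA was made from it. The labels give 4 groups of 3 biological replicates each: HDAC5 shRNA, LSD1 shRNA, a scramble shRNA set tagged as belonging to the LSD1 experiment, and a scramble set with no such tag. The untagged scramble set was assigned to the HDAC5 experiment because the other set carries the LSD1 tag and because the design text lists the 4 treatments in that order. The labels call the replicates biological, and what separates them (culture, transduction or day) is not given in the sources used here.

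The deposited values are on a log2 scale, 1 per probe set and array, and per the submitters' processing notes they were made with RMA in the affy package. RMA corrects the background, equalises the distributions of the arrays it is given and summarises the probes of a set, so a change shared by most transcripts is removed from its values and small ratios are compressed at low signal. The versions, and whether all arrays were processed together, are not given in the sources used here. Array medians were between 6.58 and 6.64 (log2) in the HDAC5 experiment and between 7.05 and 7.15 in the LSD1 experiment, which arrays brought to 1 common distribution would not show. Levels of genes were therefore compared within an experiment, apart from a difference between 2 gene lists within each array, and the comparison of the 2 scramble sets was used as a measure of the difference between experiments alone. The 12 value columns were each matched to 1 sample, and 0 columns were left over.

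Of the 22277 probe sets, 62 control probe sets were left out. Another 19064 had 1 gene symbol in the platform annotation, 1043 had several and 2108 had none. Probe sets with several symbols or none were not used for genes. Symbols were updated through the gene ID to NCBI RefSeq names of the assembly GRCh38.p14, which matched 19052 of the 19064 probe sets, and the other 12 kept the annotation's symbol. That table also gave which genes neighbour each other; no coordinates were used in the text. For each gene the probe set with the highest mean over the 12 arrays was taken, which left 11963 genes, with no filter on dim probe sets. Probe sets of 1 gene can disagree because they match different transcripts or match poorly. Those whose name ends in _x_at or _s_at can also match related genes, so the values of HLA-B, HLA-E and DLEU2 in particular can include other transcripts.

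Each shRNA was compared with the scramble arrays of its own experiment, in a fit of those 6 arrays, with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend). Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 11963 genes were called changed. Standard errors (SE) are limma's moderated ones, and SDs are over the 3 arrays of a group. The difference between the changes with HDAC5 and LSD1 shRNA, and the difference between the scramble sets, were contrasts in 1 fit of all 12 arrays. The overlap of the calls was set beside the number that independent lists would share. The 2 comparisons have no array in common. A comparison of 3 arrays with 3 cannot reach an exact two-sided permutation p under 0.1, so such p-values are given for the RNA quality measure alone. The number of arrays limits the precision.

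In all, 25 gene lists were fixed before the data were examined. They were the LSD1-CoREST complex; the HDAC, sirtuin and lysine demethylase family; MEF2 factors and targets; DNA replication; mitosis; p53 targets and CDK inhibitors; apoptosis; type I interferon response; antigen presentation; inflammatory cytokines; epithelial junctions and keratins; mesenchymal genes; extracellular matrix; TGF-beta targets; genes linked to lung or bone metastasis of MDA-MB-231 in earlier work; hypoxia and glycolysis; oxidative phosphorylation; unfolded protein and integrated stress response; cholesterol and fatty acid synthesis; ribosomal proteins; REST-repressed neuronal genes; cancer-testis antigens; and markers of luminal breast, blood, and fibroblast or endothelial cells. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists, and again with the correlation estimated from the arrays. Members past the threshold were counted over all genes and adjusted over the list alone.

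The genes named were also set by a rule fixed before the data were examined. It takes the 2 targeted genes; the 8 largest increases and 8 largest decreases per shRNA, among changed genes whose 3 shRNA arrays all lay beyond all 3 scramble arrays; up to 3 changed members of each list with the largest change, or the brightest member where none changed; the 5 genes up and 5 down with both shRNAs; and the 4 largest differences in each direction. Placeholder symbols were skipped in the top lists. The rule gave 87 genes for HDAC5 shRNA and 52 for LSD1 shRNA. Which of these are named here was chosen after their values were seen, and genes from outside the rule are marked as such where they appear, apart from those that bound a run of neighbouring genes.

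The steps were tested on simulated data with the real means and spreads. Of 100 genes changed by 0.5 (log2) among 11963, 80% were recovered in the HDAC5 comparison, 27% in the LSD1 comparison and 37% in the difference. At a change of 1 these shares were 99%, 86% and 85%, with 7, 0 and 16 false calls. The noise was drawn independently for each gene, and far fewer genes were changed than were called in the real HDAC5 comparison. These values therefore check the steps and are not rates for the real data. Windows of 20 neighbouring genes were compared with 100 permutations of the genes over their places. The alternatives tried were a filter on the dimmest 40% of probe sets, every probe set, the mean of a gene's probe sets, quantile normalization over 12 arrays, subtraction of array medians, eBayes without trend or robust, array weights, a threshold of 0.01, a 2-fold minimum, 1 fit over 12 arrays, the replicate number as a block in the HDAC5 experiment, and each array left out in turn. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.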

Results

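Gene expression was measured in MDA-MB-231 breast cancer cells that carried an shRNA against either of 2 chromatin enzymes, or a scramble shRNA. HDAC5 is a class IIa histone deacetylase, and LSD1, whose gene is KDM1A, removes methyl groups from histone lysines. The series holds 12 arrays in 4 groups of 3, with separate scramble arrays for each target, and the question its title poses is how the transcriptome differs when either enzyme is depleted. Arrays within a group were close: the pairwise correlation over all probe sets was 0.9983 to 0.9990 for the scramble arrays and 0.9985 to 0.9989 for the HDAC5 shRNA arrays of the HDAC5 experiment. In the LSD1 experiment it was 0.9945 to 0.9977 for scramble and 0.9907 to 0.9968 for LSD1 shRNA. The median SD of a gene over the 3 arrays of a group was 0.066 and 0.067 (log2) in the HDAC5 experiment, and 0.105 and 0.130 in the LSD1 experiment, so smaller changes could be called in the former. No 2 arrays were identical.

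The HDAC5 transcript had a log2 value of 7.40 ± 0.17 (SD, n = 3) in its scramble arrays and 6.29 ± 0.18 with HDAC5 shRNA. The change was -1.11 (SE 0.11, limma adjusted p = 1.61e-05), a 2.16-fold reduction. KDM1A fell from 9.72 ± 0.09 to 6.63 ± 0.17 with LSD1 shRNA, a change of -3.08 (SE 0.11, adjusted p = 6.99e-05), or 8.48-fold. Both targets were lower on all 3 shRNA arrays than on any scramble array of the same experiment. Neither shRNA passed the threshold for the other target: KDM1A differed by 0.01 (SE 0.04) with HDAC5 shRNA, and HDAC5 by 0.23 (SE 0.33) with LSD1 shRNA. HDAC5 varied widely within the LSD1 experiment, with 7.22, 7.80 and 6.85 on scramble arrays A, B and C and 7.32, 8.15 and 7.10 on LSD1 shRNA arrays 1, 2 and 3.

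**Figure D1:**
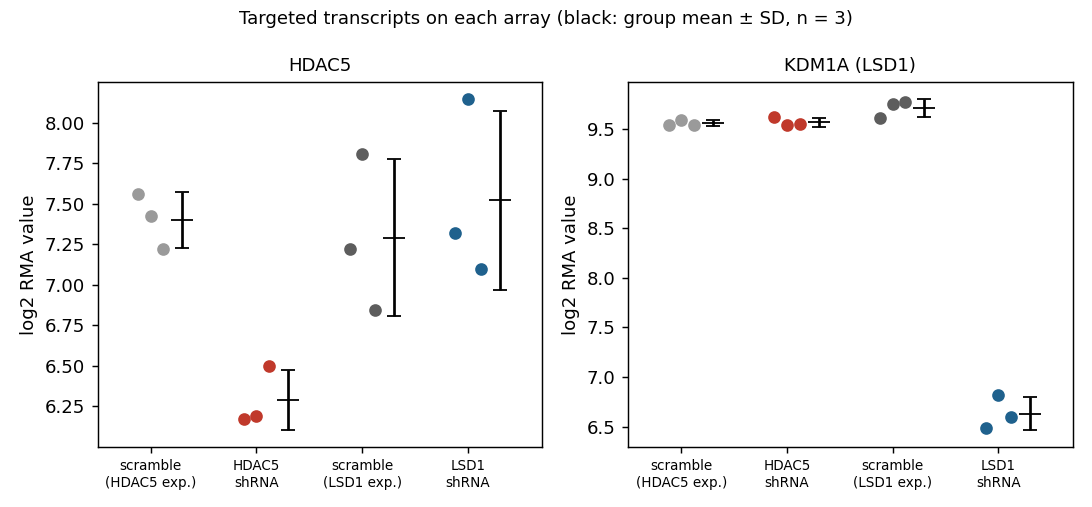
Log2 RMA values of HDAC5 and KDM1A (vertical axes, not starting at 0) on each of the 12 arrays, by group, with the group mean and SD in black (n = 3). HDAC5 shRNA arrays lie near 6.29 for HDAC5 against 7.40 in their scramble set, and LSD1 shRNA arrays near 6.63 for KDM1A against 9.72.

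With HDAC5 shRNA, genes of DNA replication and cell division rose together, and 23 of 29 genes of the unfolded protein and integrated stress response fell. All 36 measured members of the DNA replication list were higher, with a median log2 fold change of 1.33. The largest increase among named genes was that of CCNE2, the cyclin E2 gene of S phase entry, from 6.77 ± 0.38 to 10.22 ± 0.10 (change 3.44, SE 0.15, adjusted p = 8.55e-08). Next came GINS2, a subunit of the replicative helicase (2.65, SE 0.08), the E2F-family repressor E2F8 (2.61, SE 0.06), RRM2, a subunit of ribonucleotide reductase (2.52, SE 0.06), and the replication factors MCM10 (2.41, SE 0.05) and CDC6 (2.14, SE 0.07). The noncoding RNA gene DLEU2 (2.35, SE 0.06) and the exonuclease gene EXO1 (2.05, SE 0.07) completed the 8 largest increases. Of 33 genes of mitosis, 32 rose over all genes tested and 33 adjusted over the list alone, with a median of 0.82. They included the kinase gene AURKB (1.41, SE 0.06), CDC20 (1.38, SE 0.05) and the kinesin gene KIF20A (1.27, SE 0.05).

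The largest decrease was in INHBE, which encodes the inhibin beta E subunit, from 9.19 ± 0.08 to 3.87 ± 0.12 (change -5.32, SE 0.08, adjusted p = 1.76e-10). It was followed by the stress-induced cytokine gene GDF15 (-3.77, SE 0.07), TCIM (-3.76, SE 0.17) and S100P (-3.26, SE 0.07). The remaining ones were ASS1, which makes argininosuccinate (-3.15, SE 0.05), SHANK2 (-3.07, SE 0.07), TXNIP, a thioredoxin-binding protein gene (-2.95, SE 0.04), and CTH, a cysteine-making enzyme gene (-2.94, SE 0.06). INHBE and TCIM ended below the lower quartile of the HDAC5 shRNA arrays (4.59 to 4.65), where background limits the signal, so the sizes of their decreases are not exact. In the list of the unfolded protein and integrated stress response, 23 of 29 measured members fell and 4 rose (median -1.05). Its largest changes were in CHAC1, a glutathione-degrading enzyme gene (-2.84, SE 0.07), ASNS, the asparagine synthetase gene (-2.47, SE 0.04), and DDIT4, an inhibitor of mTORC1 (-2.19, SE 0.06). Of 31 inflammatory cytokine genes and regulators, 16 fell and 1 rose, with the cyclooxygenase gene PTGS2 at -1.85 (SE 0.10), ICAM1 at -1.62 (SE 0.08) and IL1A at -1.52 (SE 0.09). Of 37 extracellular matrix genes, 18 fell and 2 rose, among them TNC (-1.31, SE 0.05), COL6A2 (-0.73, SE 0.10) and LAMB1 (-0.73, SE 0.07). A further probe set of GDF15 (-0.29) did not pass the threshold, and neither did further ones of TNC, IL1A and SHANK2. With the mean of a gene's probe sets the changes were -2.03 for GDF15, -1.56 for SHANK2, -0.75 for IL1A and -0.53 for TNC, and TNC did not pass in 1 fit over 12 arrays (adjusted p = 0.0933).

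These 5 lists were the ones that camera separated from other genes, with adjusted p of 3.89e-27 for replication, 6.85e-20 for mitosis, 1.67e-09 for stress, 0.00338 for inflammatory and 0.0094 for matrix genes. With an estimated correlation none of the 5 passed (adjusted p = 0.183, 0.183, 0.261, 0.479 and 0.261). At the preset correlation 6 of the 10 splits of these arrays, the real one included, called at least 5 lists. The number of lists called thus does not set the real grouping apart. For replication, stress, inflammatory and matrix genes the counts adjusted over the list alone were the same as those over all genes. The genes that went against the rest of their list were IL11 among inflammatory genes, THBS1 and ADAMTS1 among matrix genes, and SDF2L1, CALR, DNAJC3 and PDIA6, which encode chaperones and folding factors of the endoplasmic reticulum, among stress genes. These 7 were named after their values were seen. Within an array, the mean log2 value of replication genes minus that of stress genes was -2.01 ± 0.08 (SD, n = 3) on the scramble arrays of the HDAC5 experiment and 0.39 ± 0.02 with HDAC5 shRNA, compared with 0.54 ± 0.17 on the scramble arrays of the LSD1 experiment and 0.16 ± 0.72 with LSD1 shRNA. By value it was thus the scramble set of the HDAC5 experiment that stood apart, also after quantile normalization over all 12 arrays (-2.01, 0.39, 0.53 and 0.16). Offsets of single genes between the experiments can remain in this difference. It therefore cannot decide which group of the HDAC5 experiment was the unusual one.

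In the other lists, members went both ways or changed less. Of 37 interferon response genes, 16 rose and 11 fell, with IFIT1 up by 1.25 (SE 0.05), IFI44 up by 1.00 (SE 0.05) and ISG20 at -1.07 (SE 0.08). Of 33 epithelial genes, 10 fell and 2 rose, with KRT15 at -1.23 (SE 0.08) and the claudin gene CLDN7 at -1.19 (SE 0.08). Of 21 genes linked to lung or bone metastasis, 11 fell and 5 rose, with IL13RA2 at -1.68 (SE 0.18). Among luminal markers, 8 of 18 fell and 3 rose, including the trefoil factor genes TFF3 (-1.52, SE 0.07) and TFF1 (-1.14, SE 0.08). Counts up and down were 4 and 7 of 20 for MEF2 factors and targets, with EGR1 at -1.40 (SE 0.06) and KLF4 at -1.36 (SE 0.05), and 9 and 8 of 21 for p53 targets, with GADD45A at -1.17 (SE 0.04) and FAS at 0.77 (SE 0.09). They were 9 and 6 of 23 for apoptosis regulators, with APAF1 at 1.35 (SE 0.10), although its 2 further probe sets did not pass. For hypoxia and glycolysis genes they were 10 and 9 of 30, with VEGFA at -1.16 (SE 0.07). Cholesterol synthesis genes counted 12 up and 6 down of 24, including EBP (0.82, SE 0.07) and NSDHL (0.79, SE 0.06), and ribosomal protein genes 0 up and 14 down of 27 with a median of -0.09. The tubulin gene TUBB3 (1.48, SE 0.04) was the 1 riser among 30 REST-repressed genes, 4 of which fell. HLA-B (-0.81, SE 0.06) led the 10 of 22 antigen presentation genes that fell, against 3 that rose. SIRT5 (-0.60, SE 0.06) and the targeted gene HDAC5 itself were among the 10 of 27 HDAC, sirtuin and demethylase genes that fell, besides 3 that rose. Counts up and down were 2 and 5 of 14 for the LSD1-CoREST complex, 5 and 10 of 24 for mesenchymal genes, 8 and 11 of 27 for TGF-beta targets, 12 and 4 of 34 for oxidative phosphorylation, and 3 and 1 of 21 for cancer-testis antigens. Blood markers counted 1 and 2 of 19, and fibroblast and endothelial markers 0 and 6 of 20. Adjusted over the list alone, counts up and down were 10 and 8 for p53 targets, 8 and 12 for TGF-beta targets, 11 and 9 for hypoxia, 14 and 6 for cholesterol synthesis, 0 and 19 for ribosomal and 3 and 9 for luminal genes, and the same as over all genes for the rest. With the mean of a gene's probe sets the change was 0.59 for IFI44, 0.50 for APAF1 and -0.24 for SIRT5. Camera called none of these 20 lists, but in other settings it called cholesterol synthesis genes upward, with the mean of a gene's probe sets (adjusted p = 0.00987) or without HDAC5 shRNA array 1 (0.0312), against 0.0886. It also called ribosomal protein genes downward, with the mean of probe sets (0.0475) or without scramble array 3 (0.0486) or HDAC5 shRNA array 2 (0.0233), against 0.0717. By camera with an estimated correlation, on all arrays of the experiment, neither cholesterol synthesis (adjusted p = 0.542) nor ribosomal protein genes (0.507) passed. The median and mean of the hypoxia list differed in sign (0.06 and -0.04), and those of the p53 list (both -0.01) went against its test direction, which was up.

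In total 5319 of 11963 genes changed, 2549 up and 2770 down, and 198 and 217 of these by at least 2-fold. The arrays of the 2 groups did not overlap for 50.8% of genes, where chance gives 10%. When all 12 arrays shared 1 estimate of the spread, 3512 genes were called. The 3′ minus 5′ signal of the ACTB control, a measure of RNA quality, was 0.90 ± 0.06 (log2) on scramble arrays and 0.68 ± 0.08 with HDAC5 shRNA, a difference of -0.22 (exact permutation p = 0.1, two-sided, the smallest 3 against 3 allows).

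With LSD1 shRNA, several genes of low signal on the scramble arrays rose strongly. IL13RA2, which encodes a decoy receptor for interleukin-13, went from 3.34 ± 0.39 to 11.70 ± 0.41 (change 8.37, SE 0.26, adjusted p = 4.65e-05). The type III collagen gene COL3A1 went from 4.32 ± 0.74 to 11.39 ± 0.16 (7.08, SE 0.34), the serpin gene SERPINB7 from 4.60 ± 0.07 to 10.99 ± 0.34 (6.38, SE 0.17) and SPP1, the osteopontin gene, from 3.94 ± 0.33 to 9.88 ± 0.98 (5.94, SE 0.46). The tetraspanin gene TSPAN8 (5.56, SE 0.20), EPB41L3 (5.14, SE 0.30), the interferon-induced gene IFI44L (4.67, SE 0.19) and ADGRF5 (4.60, SE 0.56) made up the rest of the 8 largest increases. TSPAN8 and ADGRF5 started higher, at 5.91 ± 0.40 and 6.64 ± 1.00. The other 6 started below the lower quartile of the scramble arrays (5.18 to 5.22), where background limits the signal, so the sizes and the order of their increases are not exact. Of 3 further probe sets of COL3A1, 2 rose (6.49 and 5.04) and 1 did not pass (0.0005), and the mean of its probe sets changed by 4.65.

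The largest decrease was in SERPINB9, the granzyme B inhibitor gene, from 7.57 ± 0.29 to 3.50 ± 0.11 (change -4.07, SE 0.15, adjusted p = 6.99e-05), although its further probe set, at -0.13, did not pass. The cadherin gene CDH11 (-3.70, SE 0.54), SLC2A10, a glucose transporter gene (-3.03, SE 0.45), DHRS2 (-2.27, SE 0.24), ATP10A (-1.98, SE 0.13), the neuropilin gene NRP1 (-1.88, SE 0.26) and REEP1 (-1.81, SE 0.11) followed, together with KDM1A itself. SERPINB9, SLC2A10 and REEP1 ended below the lower quartile of the LSD1 shRNA arrays (5.23 to 5.26), so the sizes of their decreases are not exact either. Further probe sets of NRP1 did not pass (-0.73 and -0.07), nor did that of ATP10A, and the further one of CDH11 was at -2.01. With the mean of a gene's probe sets the changes were -2.10 for SERPINB9, -1.05 for ATP10A and -0.90 for NRP1. In all 589 genes changed, 350 up and 239 down, and 124 and 40 of them by at least 2-fold. At an unadjusted p under 0.05 there were 2629. The arrays of the 2 groups did not overlap for 27.0% of genes, where chance gives 10%.

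By list, 6 of 37 interferon response genes rose and none fell, or 17 and 1 when adjusted over the list alone, with a median of 0.49. After IFI44L, the largest were IFI44 (1.31, SE 0.14) and ISG15 (0.93, SE 0.20), although a further probe set of IFI44, at 1.03, did not pass. Antigen presentation genes rose in 3 of 22 cases (4 adjusted over the list alone), namely the immunoproteasome subunit genes PSMB9 (1.56, SE 0.29) and PSMB8 (0.73, SE 0.15) and HLA-E (0.54, SE 0.10). Of 33 epithelial genes 6 rose (8 adjusted over the list alone), among them the E-cadherin gene CDH1, from 4.18 ± 0.23 to 6.40 ± 0.28 (2.22, SE 0.17), KRT15 (2.10, SE 0.35) and CLDN7 (2.07, SE 0.39). CDH1 started below the lower quartile of the scramble arrays, so the size of its rise is not exact. A further probe set of CDH1, at 0.20, did not pass, and the mean of its probe sets changed by 1.21. Of 21 metastasis-linked genes IL13RA2, SPP1 and SPARC rose and CDH11 fell. No member of the replication list (median -0.30) passed the threshold, and of the mitosis list (median -0.28) only CCNA2 did, at -0.90 (SE 0.16). Camera separated these 6 lists from other genes, with adjusted p of 2.89e-07 for interferon, 0.0258 for antigen presentation, 0.0131 for epithelial, 0.0131 for metastasis-linked, 0.000242 for replication and 1.64e-05 for mitosis genes. With an estimated correlation none passed (adjusted p = 0.303, 0.747, 0.308, 0.737, 0.747 and 0.747). At the preset correlation 7 of the 10 splits of these arrays, the real one included, called at least 6 lists. The number of lists called thus does not set the real grouping apart.

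Replicate 2 of LSD1 shRNA stood apart from the others in several of these lists. Relative to the scramble mean, the mean of the replication list was -0.79 on this array and -0.09 and -0.03 on replicates 1 and 3, and that of the mitosis list was -0.68 against -0.06 and -0.24. Without replicate 2, the replication (adjusted p = 0.203), antigen presentation (0.211) and metastasis-linked (0.137) lists did not pass, the medians of replication and mitosis genes were -0.080 and -0.097, and the total of changed genes was 786. It was 270, 111 and 104 without scramble array A, B or C and 150 and 206 without LSD1 shRNA array 1 or 3. Without scramble B and LSD1 shRNA 2 together, a choice made after seeing the data, it was 116, and 3 lists passed. The antigen presentation list also did not pass with dim probe sets left out (adjusted p = 0.0602), with the mean of a gene's probe sets (0.056) or without scramble array A (0.0658), nor did the metastasis-linked list with dim probe sets left out (0.0541). By fry, which does not compare a list with other genes, replication (0.455), mitosis (0.325) and antigen presentation genes (0.153) did not pass, while apoptosis regulators (0.0218), REST-repressed genes (0.0188) and fibroblast or endothelial markers (0.0188) did.

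**Figure D2:**
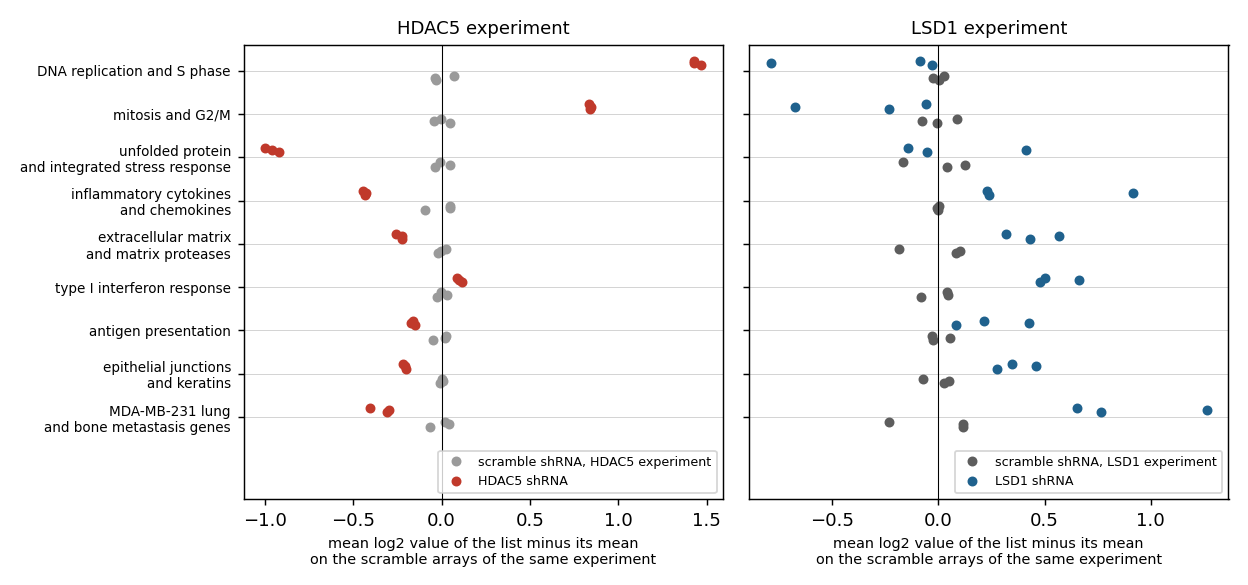
Mean log2 value of 9 gene lists on each array, minus the mean of the scramble arrays of the same experiment (horizontal axis), with scramble arrays in grey and shRNA arrays in colour. In the LSD1 experiment 1 shRNA array, replicate 2, lies at -0.79 for replication genes while replicates 1 and 3 lie at -0.09 and -0.03.

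Several single members of other lists also changed with LSD1 shRNA. Among mesenchymal genes, 4 of 24 rose and 2 fell (7 and 4 adjusted over the list alone), with the transcription factor gene TCF4 at 2.74 (SE 0.19) and fibronectin, FN1, at 2.31 (SE 0.33) beside the decrease of CDH11 and LOXL2. SPARC and PLAUR were the other members that rose. Matrix genes rose in 4 of 37 cases, namely COL3A1, FN1, LUM and COL5A2 (1.97, SE 0.23), and COL6A2 fell. Of 30 REST-repressed neuronal genes, 3 rose, namely the sodium channel gene SCN3A (3.58, SE 0.23), the synaptotagmin gene SYT1 (2.72, SE 0.30) and SCG2 (2.21, SE 0.17). Fibroblast and endothelial markers rose in 3 of 20 cases, with LUM at 1.54 (SE 0.23) and ENG besides COL3A1, while COL1A1 was at 0.05 (SE 0.08) and COL1A2 at -0.02 (SE 0.12). LUM lay below the lower quartile of the arrays in both groups (2.61 on scramble and 4.15 on LSD1 shRNA arrays), so the size of its rise is not exact. LCP1 (2.29, SE 0.35) was the 1 of 19 blood markers that rose, KRT8 (0.49, SE 0.07) and SCUBE2 were the 2 of 18 luminal markers, and COX5B (0.52, SE 0.07), NDUFA8, NDUFS1 and COX6A1 the 4 of 34 oxidative phosphorylation genes. CASP4 (0.99, SE 0.20) and DIABLO were the 2 of 23 apoptosis regulators that rose, and SERPINB5 (1.77, SE 0.22) the 1 of 21 p53 targets. Of 27 TGF-beta targets BMP4 rose. KDM1A was the 1 changed gene among 14 LSD1-CoREST members and among 27 HDAC, sirtuin and demethylase genes. Ribosomal protein genes and cancer-testis antigens each had 1 member that fell, RPL18 of 27 and MAGEA6 of 21. With the mean of a gene's probe sets TCF4 changed by 1.28 and COL6A2, at -0.53, did not pass, and the probe sets with the smallest p of FN1 and COL5A2 were at 1.42 and 1.24. SPARC, PLAUR, LOXL2, COL1A1, COL1A2, ENG, SCUBE2, NDUFA8, NDUFS1, COX6A1, DIABLO, BMP4, RPL18 and MAGEA6 were named after their values were seen. Adjusted over the list alone, counts up and down were 5 and 2 for p53 targets, 6 and 2 for apoptosis regulators, 5 and 1 for TGF-beta targets, 2 and 1 for ribosomal genes, and 3, 2 and 4 up for luminal, blood and fibroblast or endothelial markers, and otherwise the same. No member passed among 20 MEF2, 31 inflammatory, 30 hypoxia, 29 stress response and 24 cholesterol synthesis genes, where NFKBIA was at 0.62 (SE 0.25) and HSPA5 at 0.14 (SE 0.08), although NFKBIA passed in 1 fit over 12 arrays (adjusted p = 0.0460). Camera called the inflammatory list (median 0.20, adjusted p = 0.0596) in 4 other settings, upward: with array medians subtracted, a choice made after seeing the data (0.0187), and without scramble array A (0.0312) or LSD1 shRNA array 1 (0.0199) or 3 (0.00526). Without scramble array A it also called the cholesterol synthesis list downward (adjusted p = 1.41e-06), whose median moved from -0.12 to -0.36. By camera with an estimated correlation, on all arrays of the experiment, neither the inflammatory (adjusted p = 0.747) nor the cholesterol synthesis list (0.895) passed. Medians of both lists depended on single arrays: that of inflammatory genes was 0.11 without LSD1 shRNA array 2, 0.31 without array 3, 0.62 with dim probe sets left out and 0.046 without scramble B and LSD1 shRNA 2. That of cholesterol synthesis genes was 0.030 without scramble array B, -0.015 without C, -0.22 without LSD1 shRNA array 2, 0.015 without array 3, -0.069 without scramble B and LSD1 shRNA 2, and -0.058 with the mean of probe sets. Median and mean differed in sign for the lists of LSD1-CoREST, p53, oxidative phosphorylation, stress, ribosomal, cancer-testis and blood genes, none of which camera called.

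The ACTB 3′ minus 5′ signal was 1.30 ± 0.06 on scramble and 1.43 ± 0.12 on LSD1 shRNA arrays (difference 0.13, exact permutation p = 0.2, two-sided). Given the spread of the LSD1 experiment, 27% of simulated changes of 0.5 were recovered, so changes of that size can often have been missed. The share in the real data can differ from the simulated one. In 1 fit over 12 arrays 2297 genes were called, and 2053 with array weights. Of 47 genes followed through these settings, 12, 18 and 22 passed on all arrays but not without scramble array A, B or C. Without LSD1 shRNA array 1, 2 or 3, 22, 2 and 15 lost their call in this way. IL13RA2, COL3A1, SERPINB7, SPP1, TSPAN8, EPB41L3, IFI44L, SERPINB9, CDH1 and TCF4 passed in all 14 settings. In the setting with every probe set, a gene was judged by its probe set with the smallest p. Further probe sets that did not pass, as those of SERPINB9 and CDH1, therefore did not count against it there. With the mean of a gene's probe sets HLA-E (adjusted p = 0.0521), CASP4 (0.132), EGFR (0.0840) and COL6A2 (0.0742) did not pass, and without a trend ISG15 (0.0533) did not.

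Genes changed with both shRNAs numbered 327, of which 119 changed in the same direction and 208 in opposite directions, a balance that turned without LSD1 shRNA array 2. Independent lists would share 74.6 genes up and 55.3 down, where 71 and 48 were found. For genes up with HDAC5 shRNA and down with LSD1 shRNA 93 were found against 50.9, and for the reverse 115 against 81.0. Across genes, which are not independent replicates, the log2 fold changes correlated at r = -0.19 (Spearman's rho -0.20), and at r = 0.021 without LSD1 shRNA array 2. Without that array 264 genes changed in the same direction, where independent lists would share 174.1, and 219 in opposite directions, against 175.4. With array weights these were 640 against 480.1 and 622 against 484.9, with r = -0.015. Genes up with both included STYK1 (1.06 with HDAC5 shRNA, SE 0.11, and 1.17 with LSD1 shRNA, SE 0.10), IFI44 (1.00 and 1.31), COL15A1 (0.89 and 1.08), PCDH9 (0.76 and 1.04) and LMO3 (0.76 and 1.36). Genes down with both included SLC2A10 (-0.97 and -3.03), FAM149A (-0.95 and -1.59), CLGN (-0.83 and -1.03), the receptor gene EGFR (-0.78 and -1.02) and COL6A2 (-0.73 and -0.89). With LSD1 shRNA none of the 5 further probe sets of EGFR passed, nor did the further ones of COL6A2, PCDH9 and IFI44. With the mean of a gene's probe sets, PCDH9 changed by 0.30 with HDAC5 and 0.57 with LSD1 shRNA and FAM149A by -1.01 with LSD1 shRNA, and EGFR was at -0.36 with HDAC5 shRNA and at -0.28 with LSD1 shRNA, where it did not pass. In 1 fit over 12 arrays SLC2A10 did not pass with HDAC5 shRNA (adjusted p = 0.0598). The count in the same direction rested on the LSD1 arrays: it was 60, 16 and 19 without scramble A, B or C, and 19 and 34 without LSD1 shRNA array 1 or 3.

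**Figure D3:**
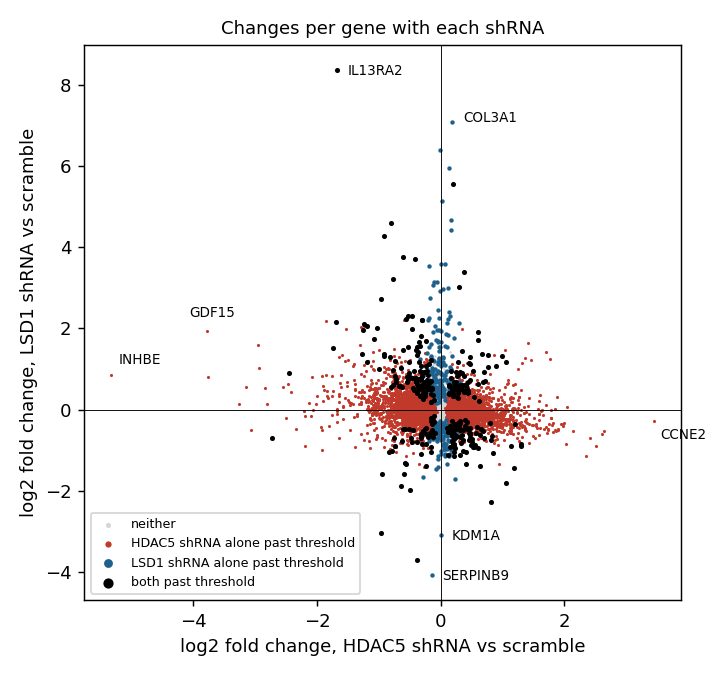
Log2 fold change with LSD1 shRNA (vertical) against that with HDAC5 shRNA (horizontal) for 11963 genes, coloured by which comparison passed an adjusted p of 0.05. Among the largest changes are CCNE2 at 3.44 and INHBE at -5.32 with HDAC5 shRNA and COL3A1 at 7.08 with LSD1 shRNA, while IL13RA2 changed in opposite directions, 8.37 with LSD1 shRNA and -1.68 with HDAC5 shRNA.

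The difference between the changes, tested in 1 fit, passed for 3803 genes, 1877 with the higher value under HDAC5 shRNA and 1926 with the higher value under LSD1 shRNA. In the former direction the largest were SERPINB9 (difference 3.93, SE 0.18, or 2.10 with the mean of its probe sets), CCNE2 (3.71, SE 0.48), DLEU2 (3.49, SE 0.44) and RRM2 (3.42, SE 0.42). In the latter they were IL13RA2 (-10.05, SE 0.36), COL3A1 (-6.89, SE 0.37), SERPINB7 (-6.40, SE 0.19) and INHBE (-6.18, SE 0.74). SERPINB9 and the last 4 rest on a group mean below the lower quartile of its arrays, so these sizes and their order are not exact. KRT15 and CLDN7 fell with HDAC5 shRNA and rose with LSD1 shRNA, and the difference passed for both (-3.33, SE 0.38, and -3.26, SE 0.42). By list, the difference was positive for all 36 replication genes (median 1.56, camera adjusted p = 4.16e-24) and 31 of 33 mitosis genes (1.09, adjusted p = 1.61e-18), and 32 of the latter adjusted over the list alone. It was negative for 19 of 29 stress genes and positive for 4 (median -0.98, adjusted p = 0.0001), or 20 and 4 adjusted over the list alone. With an estimated correlation these did not pass (adjusted p = 0.359, 0.359 and 0.416). For IFI44 (-0.31, SE 0.15, adjusted p = 0.155) and EGFR (0.24, SE 0.15, adjusted p = 0.252) the difference did not pass.

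The 2 scramble sets differed in 9102 of 11963 genes, 1425 higher in the HDAC5 experiment and 7677 lower, around a median difference of -0.41 (log2). After quantile normalization over all 12 arrays 7957 genes still differed, of which 49.1% were higher in the HDAC5 experiment, compared with 15.7% as deposited, and 5474 were called in the same direction as before. Subtraction of array medians, which moves all genes of an array alike, left 7972, with 52.6% higher. Cultures, array runs and normalization cannot be told apart in this comparison, which is why each shRNA was set against its own scramble arrays.

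**Figure D4:**
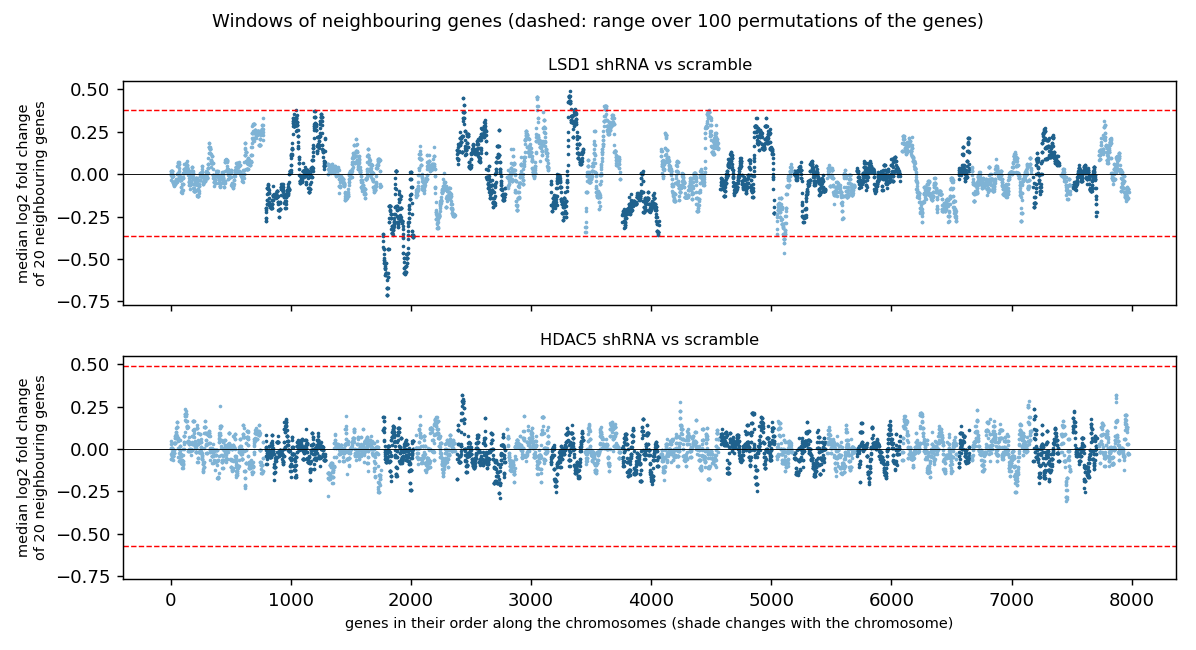
Median log2 fold change of windows of 20 neighbouring genes (vertical axis) along the chromosomes in order (horizontal axis, 7995 genes above the dimmest 40% of probe sets), for LSD1 shRNA (top) and HDAC5 shRNA (bottom), with the range over 100 permutations of the genes dashed. With LSD1 shRNA 152 windows lie outside that range, the lowest at -0.71, and with HDAC5 shRNA 0 do.

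With LSD1 shRNA, neighbouring genes shifted together in places. Of 7556 windows of 20 neighbouring genes, 152 had a median beyond all 100 permutations, in 10 runs, 4 of them lower and 6 higher. The lowest windows lay between ATP5ME and TBC1D1, a run of 64 genes with a median of -0.44, and the same chromosome held 2 more lowered runs, from NFKB1 to FBXW7 (61 genes, median -0.46) and from PALLD to PDLIM3 (24 genes, -0.36). Of the 239 genes down with LSD1 shRNA, 228 were placed in this scan and 53 of them (23.2%) lay in lowered runs. In the HDAC5 comparison 0 windows were beyond all permutations, whose range was wider there (-0.57 to 0.49, against -0.36 to 0.38), so shifts of the size of most of these runs would not have been found. The run from TDP2 to H2AC14 had a median of 0.33 with LSD1 shRNA and 0.23 with HDAC5 shRNA.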

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

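The tests of the culture state, with the values of the 4 groups, of normalization and of the HDAC5 level for the first pattern, of the culture state for the second and of other cell types and copy gain for the third were chosen after the result was seen, and the criterion for the HDAC5 level was made stricter after its value was known.

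The changes with the 2 shRNAs differed, by a test of the difference itself, in the targeted genes: the log2 fold change with HDAC5 shRNA minus that with LSD1 shRNA was -1.34 for HDAC5 and 3.09 for KDM1A. Among the genes named for the largest differences it was 3.93 for SERPINB9, 3.71 for CCNE2, 3.49 for DLEU2, 3.42 for RRM2, -10.05 for IL13RA2, -6.89 for COL3A1, -6.40 for SERPINB7 and -6.18 for INHBE. Of the gene lists, 11 differed: the median difference was 1.56 for replication, 1.09 for mitosis, -0.24 for interferon, -0.38 for antigen presentation, -0.20 for inflammatory, -0.21 for epithelial, -0.35 for matrix, -0.67 for metastasis-linked, -0.98 for stress, -0.28 for luminal and -0.15 for fibroblast or endothelial genes. None of the 11 passed with an estimated correlation (adjusted p between 0.142 and 0.577), and 5 did not pass in other settings either. With dim probe sets left out these were interferon (0.0521), matrix (0.145), metastasis-linked (0.145) and luminal genes (0.0884). Metastasis-linked genes also did not pass without LSD1 shRNA 2 (0.0746), alone or with scramble B (0.104), nor luminal genes without scramble A (0.0833), LSD1 shRNA 1 (0.0700) or LSD1 shRNA 2 (0.0542). Fibroblast or endothelial genes did not pass with the mean of probe sets (0.0627), after quantile normalization (0.116), or without scramble 3 (0.0672) or shRNA 2 (0.0663) of the HDAC5 experiment, scramble B (0.0583) or LSD1 shRNA 1 (0.0887). The size of the median difference also moved by more than 1.5 times in 5 lists: with dim probe sets left out it was -1.25 for inflammatory, -0.15 for matrix and -0.72 for fibroblast or endothelial genes, and the last was at -0.071 with the mean of probe sets, -0.094 after quantile normalization and -0.091 with array medians subtracted. For metastasis-linked genes it was -0.37 without HDAC5 shRNA 1, -0.33 without scramble A and -0.44 and -0.35 without LSD1 shRNA 2 and 3, and for antigen presentation -0.23 without LSD1 shRNA 2. Beyond the 11, the difference passed for hypoxia genes without HDAC5 shRNA 1 (0.0462) or scramble A (0.0393), for cholesterol synthesis genes without scramble A (1.81e-05) or LSD1 shRNA 2 (0.031), and by fry for mesenchymal (0.018), TGF-beta (0.0487), ribosomal (0.00207) and REST-repressed genes (0.00207). Probe sets with no gene name, which entered no comparison above, also held changes: 477 of 2108 passed the threshold with HDAC5 shRNA and 51 with LSD1 shRNA. Single outlying arrays were not tested, because the rule used here takes groups of at least 4 arrays.

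The first pattern is the rise of replication genes and fall of stress genes with HDAC5 shRNA. A trend with signal left by normalization does not account for it, since the median difference (log2) from the change of genes matched in signal was 1.35 for replication and -1.06 for stress genes. The mean of replication genes minus that of stress genes within an array was -2.01 ± 0.08 (SD, n = 3) in the scramble set of the HDAC5 experiment, 0.39 ± 0.02 with HDAC5 shRNA, 0.54 ± 0.17 in the scramble set of the LSD1 experiment and 0.16 ± 0.72 with LSD1 shRNA. By value the first of these groups stood apart. Offsets between the experiments can remain in this difference, so it does not decide whether this scramble set or the HDAC5 shRNA arrays were unusual. A culture state that varies without HDAC5 shRNA, in that scramble set or in the shRNA arrays, may contribute: across genes, which are not independent replicates, the HDAC5 shRNA changes had r = -0.69 with LSD1 shRNA replicate 2 minus the mean of replicates 1 and 3, arrays that share nothing with the HDAC5 comparison. An effect of the HDAC5 level stays open, as over the 6 arrays of the LSD1 experiment it had r = -0.80 with this score (exact permutation p = 0.0403, adjusted 0.0806; Spearman's rho -0.49, p = 0.356), but r = 0.68 without LSD1 shRNA 2 and scramble B, the 2 arrays farthest from the median HDAC5 level and the 1 pair of 15 whose removal turned the sign (r = -0.78 without the 2 farthest from the mean), so the relation rests on that pair.

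The second pattern is the runs of neighbouring genes shifted with LSD1 shRNA. From LSD1 shRNA replicate 1 and scramble A alone 7 runs were found, and 100% of them shifted the same way in the other 4 arrays. A single array does not account for these 7. They are not the same set as the 10 runs found from all arrays. The runs that start at NUFIP1, PALLD, DNAJC2, ZFP37 and SLC67A2 were not found from that pair and had no such check. For the 10 runs as a set, the median shift with HDAC5 shRNA was 4.42% of that with LSD1 shRNA (95% bootstrap interval over runs -5.52% to 12.5%). A culture state shared with the HDAC5 comparison therefore does not account for the set. It stays open for the run from TDP2 to H2AC14, singled out after its value was seen, at 69.0% (over genes 9.03% to 377.3%). A culture state particular to the LSD1 experiment could not show in the HDAC5 comparison and stays open for all runs. A candidate explanation is another copy number in the cells that carried LSD1 shRNA or in the scramble cells of that experiment, as in a subclone. The values do not tell which group departed. In the median of the 7 runs found from the pair, 87.1% of genes shifted its way in the other 4 arrays. Regional regulation after loss of LSD1 was not tested and stays open.

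The third pattern is the strong rise of genes of low signal with LSD1 shRNA. Fibroblasts or endothelial cells in the cultures do not account for it: without COL3A1, the list of their markers had a median change of 0.0208. COL1A1 (7.89 to 7.93), COL1A2 (5.18 to 5.16) and DCN (5.40 to 5.44) stayed near their scramble values, although LUM and ENG rose. ACTA2 was also higher (6.15 to 7.22) but did not pass the threshold (limma adjusted p = 0.0616). DCN and ACTA2 were named after their values were seen. Copy gain of the raised runs does not account for most of the third pattern, since 5 of the 124 genes up at least 2-fold (4.03%) lay in those runs. Of all 11955 genes with a position, dim ones included, 276 did (2.31%). Gains too short for windows of 20 genes were not tested. An effect of LSD1 loss on these genes was not tested separately and stays open, as does selection of a subclone.

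For the numbers of genes called, 10 splits of 6 arrays are too few for a share under 0.05: the real splits gave 5319 genes with HDAC5 shRNA, 589 with LSD1 shRNA and 9102 between scramble sets, and the highest other split gave 0 in each. For the lists the real splits gave 5 and 6, and the highest others 6 and 10, with 6 and 7 of the 10 splits giving as many. The numbers of lists called at the preset correlation therefore do not set the real groupings apart from other groupings of the same arrays. Over 100 of 200 splits, 1 gave as many genes that differ as the real 3803 (highest other 2737). That share is under 0.05 and speaks against chance in the groupings of both experiments at once, that is, against no real change in either. It does not decide on chance in the grouping of 1 experiment alone. A real change in the other could make the real split the largest, and 10 splits per experiment are too few. For the real 119 in the same direction, 1 of 100 splits gave as many (highest other 0), which decides nothing, because every other split of an experiment calls 0 genes and leaves none to share. For the 11 lists that differ, 2 of 100 splits gave as many and the highest other also gave 11. This share is under 0.05, but it says nothing of single lists, none of which passed with an estimated correlation.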

How the results depend on the processing

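The setting that leaves out scramble B and LSD1 shRNA 2 together, the lists with array medians subtracted, the difference between replication and stress genes within an array and the correlation of fold changes in each setting were chosen after the result was seen; all others were planned. Each targeted gene kept its direction and side of the threshold with its own shRNA in all 14 settings, with ranges without 1 array of -1.22 to -1.03 for HDAC5 and -3.18 to -3.01 for KDM1A. With the other shRNA neither passed in any setting, but the sign turned: HDAC5 was at -0.08 without LSD1 shRNA 2, and KDM1A at -0.03 with quantile normalization, -0.02 without HDAC5 shRNA 1 and -0.0018 without scramble 3. Counts with HDAC5 shRNA were 4563 to 5046 genes without 1 array, 415 at 2-fold and 3512 in 1 fit over 12 arrays. With LSD1 shRNA they were 104 (without scramble C) to 786 (without LSD1 shRNA 2), 2053 with array weights, 115 at an adjusted p under 0.01, 164 at 2-fold, 2297 in 1 fit over 12 arrays and 116 without the pair of arrays, 107 of them shared with the 589. Genes that differ numbered 2347 at 0.01 and 903 at 2-fold, and the scramble sets 6044 with dim probe sets left out (fewer genes tested) and 2096 at 2-fold. Genes changed in the same direction numbered 16 (without scramble B) to 264 (without LSD1 shRNA 2), 640 with array weights, 14 at 0.01, 2 at 2-fold, 296 in 1 fit and 25 without the pair. Opposite changes outnumbered these in every setting except without LSD1 shRNA 2 and with array weights. The correlation of fold changes was -0.29 (without LSD1 shRNA 3) to 0.021 (without LSD1 shRNA 2), where it reversed. The 1 fit changes only how the spread is estimated, while array weights also change the fold changes; beyond that the cause was not tested. Lists called with HDAC5 shRNA were 0 with an estimated correlation and 20 with fry, which does not compare a list with other genes, and there the p53 list, with a median of -0.012, reversed direction. With LSD1 shRNA they were 0 with an estimated correlation, 3 without the pair, and 3 (without LSD1 shRNA 2) to 7 (without scramble A), and for the difference 0 with an estimated correlation and 7 with dim probe sets left out. Of 770 values of named genes with HDAC5 shRNA 768 kept their call, of 658 with LSD1 shRNA 542 did, and of 152 for the difference all did. These include the setting with every probe set, which judged a gene by its probe set with the smallest p and is a lenient check.

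With the replicate number as a block, 4869 genes changed with HDAC5 shRNA, 3035 differed, 109 changed in the same direction and 5 lists were called. In the HDAC5 experiment the numbers do not pair the arrays: same-numbered deviations had r = -0.05, -0.21 and -0.15. In the LSD1 experiment scramble arrays are lettered and shRNA arrays numbered, so the labels give no pairs, and neither a block nor this check was run. Signal close to background limits fold changes of dim genes, which RMA compresses.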

Other observations

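The descriptions in this part were chosen after the result was seen. With LSD1 shRNA, the chromosome that holds the runs from ATP5ME to TBC1D1, NFKB1 to FBXW7 and PALLD to PDLIM3 had a median log2 fold change of -0.32 over its 274 placed genes, of which 80.3% were below 0. The next lowest of the 22 chromosomes with at least 100 placed genes had -0.20 over 322 genes, with 81.1% below 0 and no run, and the third had -0.14, with 72.0% below 0. The other lowered run went from NUFIP1 to OR7E156P (27 genes, median -0.41). Raised runs went from ELOC to MTDH (39 genes, 0.41), SPAG1 to MRPL13 (30 genes, 0.32), DNAJC2 to CAPZA2 (27 genes, 0.30), TDP2 to H2AC14 (28 genes, 0.33), ZFP37 to DENND1A (32 genes, 0.38) and SLC67A2 to ACTR3 (20 genes, 0.38). In all 10 runs the 3 LSD1 shRNA arrays lay on the run's side. The runs held 4.40% of placed genes and, in their own direction, 81 of the 486 placed genes that changed (16.7%): 23.2% of those down and 10.9% of those up.

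With HDAC5 shRNA, 137 genes had another probe set past the threshold in the opposite direction, and with LSD1 shRNA 0 did, so the direction of those 137 depends on the probe set. Many further probe sets of changed genes did not pass at all. With HDAC5 shRNA 1760 did not pass and 1765 passed in the same direction. With LSD1 shRNA 276 (of 189 genes) did not pass and 129 (of 94 genes) passed in the same direction.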
